A study of Homo sapiens with 12 samples.

How the data were processed

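The series held 12 libraries from MCF10A-NeuT cells, a human mammary epithelial line transformed with the NeuT oncogene. They fell into 6 groups of 2 libraries by the labels' titles: input DNA and PPARγ chromatin immunoprecipitation (ChIP) from cells that carried empty vector, wild-type PPARγ or the mutant that the labels call KQ, in which a pair of neighbouring lysines was replaced by glutamine. A peak list was used for the 4 ChIP libraries of the wild-type and KQ groups, together with 1 list from the pooled libraries of each of these groups, 6 lists in all. The vector ChIP libraries and all input libraries were not analysed here. The labels do not say whether replicates came from separate cultures, so the spread between libraries may be technical. The labels disagree on the pull-down: the antibody field and the extraction protocol name a PPARγ antibody, and the series' design text names an antibody to the Flag tag. With a PPARγ antibody, receptor made from the cells' own gene would be pulled down as well. The design text also calls the mutant acetylation deficient, although glutamine is often used to mimic an acetylated lysine. The growth protocol names a further mutant line that has no libraries in the series.

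Per the submitters' processing notes, reads were mapped to the hg38 build with Bowtie2 (version 2), peaks were called with MACS2, and bedtools, deepTools and HOMER were also named. Caller settings and the use of input as a control are not given in the sources used here. The authors called peaks in each library and again on the pooled libraries of a group. Each deposited list gives, per peak, a fold enrichment over the caller's background, which is a ratio made by the authors. The deposited lists also give −log10 of the q-value of each peak, with a lowest value between 1.30 and 1.41, and the authors' summit position. Fold and q are the authors' values throughout. They served to describe, rank and filter peaks within a list and to compare shared with unshared peaks of the same list. Fold and p also served to recover tag depth, which was compared between the lists.

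Peaks on chromosomes 1 to 22 and X were used. No intervals within a list overlapped, so merging changed nothing. Peaks were compared by an overlap of at least 1 bp. A pooled peak that overlapped a peak in both libraries of its group is called reproducible. Overlap by position alone came from 1000 circular shifts of a list within each chromosome, with a one-sided p of which 9.99e-04 is the smallest value possible. Peak counts per library were compared with an exact permutation test, two-sided, which with 2 against 2 cannot go below 0.33. Fold enrichment of shared and unshared wild-type peaks was compared with a permutation test of medians on the log2 scale with 100000 resamples, two-sided. Peaks are not replicates, so the tests over peaks describe these lists. The p-values over libraries concern these samples only. They stand at their floor whenever the groups separate fully, whatever the spread.

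Gene positions came from the RefSeq table of GRCh38.p14, the same assembly as hg38, with 19970 protein-coding genes on these chromosomes. The table used here gives gene spans without strand, exons or transcription start sites. The planned start-site windows were therefore replaced by the gene span extended by 50 kb on each side, and promoters by gene ends, meaning summits within 1 kb of either end of a protein-coding gene. Exons, introns and untranslated regions were not told apart. Location was compared with Fisher's exact test. No genome sequence was used here, so the planned search for PPAR response elements was not run.

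The text names 20 gene lists fixed before the data were examined: PPAR targets and fatty acid use, adipocyte differentiation, cholesterol synthesis and uptake, glycolysis, autophagy, cell cycle, apoptosis, basal mammary epithelium, luminal mammary epithelium, mesenchymal transition and matrix, inflammatory mediators and NF-kB, angiogenesis and hypoxia, ERBB and growth factor signalling, nuclear receptors and coregulators, stem cell with Wnt and Notch, Hippo and AP-1, ribosomal proteins, and markers of hepatocytes, neurons and blood cells. The share of members with a reproducible peak was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists within a group and a threshold of 0.05. Longer genes have wider windows, so 10000 random lists matched on gene length in 20 bins were added after the data were seen. Genes that share a peak are not independent in these tests. Wild-type and KQ were compared over the members by an exact McNemar test after the reproducible wild-type list was shortened to the KQ length by q. So few genes then differed that 1 of the 20 lists could have passed the threshold before adjustment and 0 after it.

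Genes were named by a rule fixed beforehand: the gene nearest to each of the 10 highest-fold reproducible peaks of each group and to the 5 highest-fold KQ peaks with no overlap in any wild-type list, up to 3 members of each gene list per group with the highest-fold reproducible peak, and PPARG, ANGPTL4, PDK4, PLIN2, CPT1A and FABP4. Genes outside the rule are named as examples chosen after their values were seen. Some genes that the rule or the lists cover are not reported here.

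The tag depth of each list was recovered from the caller's values. Fold and p of a peak fix its tag pileup and local background, because fold is the pileup plus 1 over the background plus 1 and p is a Poisson tail. In every list 100% of the peaks gave a whole pileup, to within 0.001 on the −log10 p scale. Had ChIP tags been scaled down to a smaller control, far fewer would be whole, 9.0% to 48.4% in 4 simulations. A control scaled to the ChIP tags, or no control, leaves the lowest background on the scale of the ChIP tags, and a control left unscaled would not. The lowest background shared by at least 5 peaks, over the shortest peak, which was taken as the fragment length, gives a background rate in tags per kb. Intervals on shares are exact binomial at 95% over peaks. They cover counting error only, since peaks are not replicates and the spread between libraries is left out. Tags without molecular identifiers are not independent molecules either.

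The code was tested on simulated data. All 200 planted overlaps among 2846 peaks were recovered, and 0 of 40 simulated unrelated lists passed the shift test. These lists were simulated, so their result checks the code only. It gives no rate of false calls for real peak lists, which may share regions for reasons other than binding of the same receptor. Of the simulated gene lists among 19970 genes, 200 of 200 with planted peaks and 3 of 200 random lists had an unadjusted p under 0.05. Each planted list of 40 genes held 32 near a peak. Its 200 runs were therefore the same test repeated, which checks the code and does not measure power. For the pileups, 499 of 499 simulated values were recovered. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered stricter q thresholds, other overlap rules, other gene windows, length-matched lists, single libraries and the replicate number as a block. For gene lists and location, leaving out a library leaves all peaks of the other library in place of the reproducible peaks, so the library and the filter change together.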

Results

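The series asked how replacing a pair of lysines of PPARγ by glutamine changes where the receptor binds DNA. PPARγ is a nuclear receptor that controls fat storage and fatty acid use, and it was mapped here by ChIP-seq in transformed mammary epithelial cells. The labels give 2 ChIP libraries for wild-type PPARγ and 2 for the KQ mutant. The wild-type libraries had recovered background rates of 2.69 and 1.13 tags per kb, and the KQ libraries had 3.61 and 3.56. If the caller's background was on the scale of the ChIP tags, the KQ libraries were the deeper ones. The use of an input control is not given in the sources used here. The rates of the pooled lists, 3.8 for wild type and 7.15 for KQ, lay close to the sums of their libraries.

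Wild-type PPARγ gave far more peaks than the KQ mutant. The wild-type libraries had 18143 and 17859 peaks, and the KQ libraries had 1263 and 1035. The means were 18001 ± 201 peaks (SD, n = 2) for wild type and 1149 ± 161 (SD, n = 2) for KQ. The ratio of 15.7 was larger than the spread within either group, although the exact permutation test cannot go below p = 0.33 with n = 2 per group, which is the value it gave. The covered length followed the counts, at 3.76 and 3.14 Mb for wild type against 0.281 and 0.216 Mb for KQ, a ratio of 14.0 (exact permutation p = 0.33, n = 2 per group). Median peak width was 189 and 155 bp in the wild-type libraries and 205 and 195 bp in the KQ libraries. The pooled lists held 25164 wild-type and 2846 KQ peaks, a smaller ratio of 8.84, and the ratio of their covered lengths was 8.36.

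**Figure D1:**
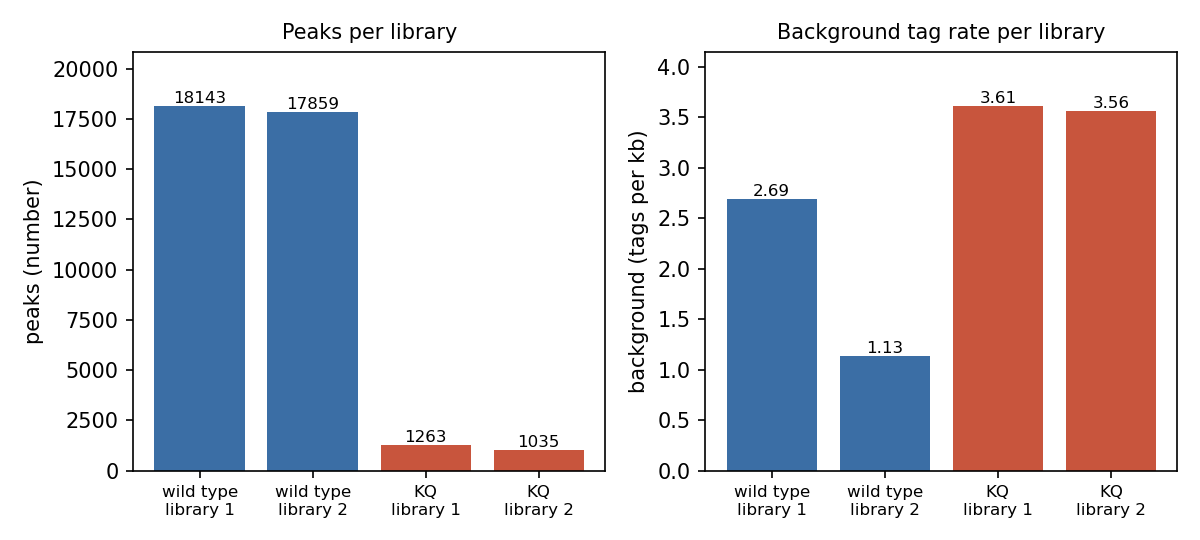
Number of peaks (left) and recovered background rate in tags per kb (right) for each of the 4 ChIP libraries, 1 bar per library and both axes from 0. The wild-type libraries hold 18143 and 17859 peaks at 2.69 and 1.13 tags per kb, and the KQ libraries 1263 and 1035 peaks at 3.61 and 3.56.

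Nearly all KQ sites that recurred between libraries were also wild-type sites. Of the 2846 pooled KQ peaks, 2289 (80.4%, 95% interval 78.9 to 81.9) overlapped a pooled wild-type peak, against a mean of 10.7 after circular shifts (one-sided permutation p = 9.99e-04, the smallest possible). In the reverse direction 9.10% of the 25164 wild-type peaks overlapped a KQ peak. Shortening the wild-type list to the KQ length by q lowered the KQ share to 35.7%, since the full wild-type list is longer. Among the 354 reproducible KQ peaks, 340 (96.1%) overlapped the pooled wild-type list and 10 (2.82%, 95% interval 1.36 to 5.13) overlapped no wild-type list. Of the 8033 reproducible wild-type peaks, 1618 (20.1%) overlapped a pooled KQ peak.

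Libraries of the same group shared between 28.0% and 45.0% of their peaks. Wild-type library 1 shared 44.1% of its peaks with library 2, and 45.0% in the other direction. The KQ libraries shared 28.0% and 34.1%. KQ library 1 shared 74.8% of its peaks with wild-type library 1 and 68.8% with wild-type library 2, and for KQ library 2 these shares were 74.3% and 66.4%. These shares depend on list length, and the wild-type lists are the longer ones.

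The wild-type sites found again with KQ were the stronger ones. Within the pooled wild-type list, the median fold enrichment was 9.0 for the 2289 peaks shared with KQ and 6.01 for the 22875 unshared peaks, a difference of 0.58 on the log2 scale (permutation test, two-sided, p = 1e-05, the smallest possible). The difference was 0.48 in wild-type library 1 and 0.55 in library 2. In the highest of 10 equal bins of wild-type peaks by −log10 q, 37.5% (95% interval 35.6 to 39.4) overlapped a KQ peak and 97.6% were present in both wild-type libraries. In the lowest bin these shares were 2.74% and 0.44%.

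**Figure D2:**
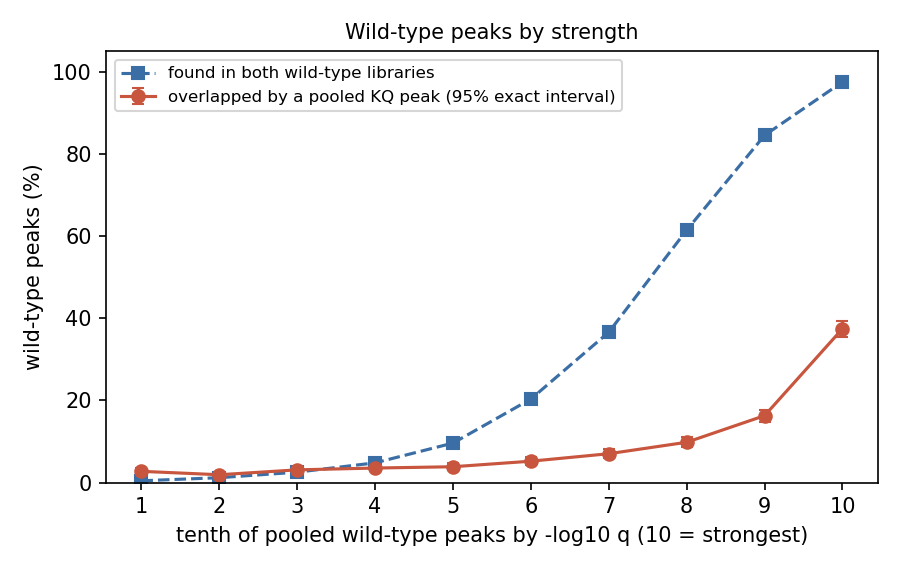
Share of pooled wild-type peaks, in percent, that were overlapped by a pooled KQ peak (circles, bars are exact 95% binomial intervals) or found in both wild-type libraries (squares), in 10 equal bins of −log10 q. The KQ share is 37.5% in the strongest bin, where 97.6% of the peaks are in both wild-type libraries.

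The highest-fold wild-type peaks lay near genes of varied function, and most had a KQ peak. The highest fold of a reproducible wild-type peak was 35.2, at 111078836 to 111079231 on chromosome 13 (hg38), 35.6 kb outside the span of ARHGEF7. It overlapped no pooled KQ peak, and neither did the peak inside CNTN4 (fold 29.4, chromosome 3, 2872920 to 2873160), which encodes a neuronal adhesion molecule. The other 8 of the 10 did overlap one. They lay inside MGST3 (fold 34.9), a microsomal glutathione transferase, NPSR1 (34.7), GNB1L (32.8), SEMA5A (30.2), PEMT (30.0), ENPP1 (29.9) and TRHDE (29.1), and 3.8 kb outside PGLYRP4 (32.6). PEMT makes phosphatidylcholine, and ENPP1 releases pyrophosphate from nucleotides.

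The highest-fold KQ peaks also lay near genes of varied function. The KQ list was led by a peak inside IFT122 (fold 16.2, chromosome 3, 129485760 to 129486166), which acts in cilium transport. It was followed by peaks inside HADHB (fold 15.2, chromosome 2, 26274046 to 26274436), a subunit of the trifunctional protein of beta-oxidation, and inside ACADVL (fold 15, chromosome 17, 7220190 to 7220513), the very long chain acyl-CoA dehydrogenase. The others were near TMEM170B (14.7), TLN2 (14.3), TRHDE (14.0), PARD3 (13.8), FFAR2 (13.7), LOC124907920 (12.9) and CDK12 (12.6). The FFAR2 peak lay 7.7 kb outside that fatty acid receptor gene, and the peak assigned to PARD3 lay 303.5 kb from it. All 10 overlapped a pooled wild-type peak, and the TRHDE site was among the 10 highest in both groups.

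The KQ peaks with no wild-type overlap numbered 508, or 17.9% of the pooled list. The 5 with the highest fold were nearest to GULP1 (11.0), MYO18B (8.50), BCAS1 (8.50), TMEM245 (8.13) and SUCLG1 (8.01). The peaks assigned to GULP1 and SUCLG1 lay 309.0 and 507.9 kb from these genes. The TMEM245 peak lay 0.3 kb outside its gene and the MYO18B peak inside. Of the 5, only the BCAS1 peak (chromosome 20, 53907138 to 53907414, 36.3 kb from the gene) was present in both KQ libraries.

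Known PPARγ target genes also had sites in the KQ list. Binding of the mutant was not told apart here from that of the cells' own receptor. ANGPTL4, CPT1A, PDK4, PLIN2 and FABP4 each had a reproducible peak within 50 kb in both groups. The highest wild-type fold was 25.5 at ANGPTL4, an inhibitor of lipoprotein lipase, 26.1 at CPT1A, which brings fatty acids into mitochondria, 20.2 at PDK4, which restrains pyruvate use, 23.6 at PLIN2, a lipid droplet coat protein, and 21.7 at FABP4, a fatty acid carrier. The KQ peaks in the ANGPTL4 gene (chromosome 19, 8367337 to 8367711), in CPT1A (chromosome 11, 68839269 to 68839495) and near PDK4 (chromosome 7, 95608719 to 95609140) lay on the highest wild-type peak of the gene. At PLIN2 and FABP4 the reproducible KQ peak lay on another site of the window, and the highest wild-type peak overlapped a pooled KQ peak not found in both KQ libraries. PPARG itself had 9 pooled wild-type peaks, 1 of them reproducible (fold 11.0), and 0 KQ peaks in any list.

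Sites near PPAR targets and fatty acid genes were over-represented in both groups. With wild-type PPARγ, 39 of the 46 genes (84.8%) had a reproducible peak, against 37.6% of other genes (Fisher's exact test, adjusted p = 1.29e-09). With KQ, 15 of 46 (32.6%) had one against 2.61% of other genes (exact test, adjusted p = 1.03e-11). CPT1B had the highest wild-type fold of the list (28.7) and also had a KQ peak. HADHA shared its 2 KQ sites with HADHB, and UCP2 and UCP3 shared a site. ACSL3, ECH1 and CAT also had a KQ peak, whereas CD36, SCD, LPL and ACSL1 had reproducible peaks with wild type and pooled KQ peaks that were not reproducible. When the wild-type list was shortened to the 354 strongest peaks, 18 of the 46 genes had a peak with wild type, 15 with KQ and 13 with both (exact McNemar test, p = 0.453). The 7 genes that differed allow no adjusted p below 0.312, so this comparison could not have shown a difference over the 20 lists.

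Adipocyte differentiation genes were also called in both groups, by a narrow margin with KQ. With wild type 21 of 26 genes (80.8%) had a reproducible peak (exact test, adjusted p = 1.35e-04), among them CEBPA (fold 23.1) and PLIN1 (21.1). The odds ratio of 6.95 was 17.4 with all peaks of wild-type library 1. With KQ 4 of 26 had one (exact test, adjusted p = 0.0477), namely FABP4, PLIN1, EBF1 and RETN, of which the first 2 are also on the PPAR list. The KQ call was lost with length-matched lists (permutation test, adjusted p = 0.0760), with the 5 kb window (exact test, 0.185) and with the nearest gene to each summit (0.193), although the odds ratio of 6.65 was 7.65 in the 5 kb window. It held with all pooled peaks (exact test, adjusted p = 7.42e-04), with all peaks of KQ library 2 (5.47e-06) and with all peaks of KQ library 1 (0.00926). At matched list length 6 genes had a peak with wild type and 4 with KQ (exact McNemar p = 0.625), and the 4 that differed allow no exact p below 0.125 before adjustment.

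With wild type, 3 further lists passed the threshold. Basal mammary epithelium had 18 of 24 genes with a peak (75%, exact test, adjusted p = 0.00272), including CDH3 (22.4), CAV1 (17.9) and LAMB3 (17.1). The CDH3 peak lies outside that gene and inside the luminal gene CDH1. The LAMB3 peak lies outside LAMB3 and is also the highest-fold peak of G0S2 on the PPAR list. Autophagy had 18 of 26 (69.2%, exact test, adjusted p = 0.00859), including ULK2 (24.1) and GABARAP (23.6), whose peak is the ACADVL site. Nuclear receptors and coregulators had 17 of 26 (65.4%, exact test, adjusted p = 0.0283), including RARB (14.5), NR1H3 (14.2) and ESRRA (11.1). This call was lost with length-matched lists (permutation test, adjusted p = 0.142). In the wild-type list shortened to the KQ length 0 of its genes had a peak, and the basal and autophagy calls were lost as well (exact test, adjusted p = 0.522 and 0.255). The autophagy odds ratio was 3.90 there against 3.72 with the full reproducible list, and that of basal epithelium was 2.71 against 4.96. The calls for basal epithelium and autophagy were lost in a 5 kb window (exact test, adjusted p = 0.157 and 0.285), with the nearest gene to each summit (0.255 for both) and with all peaks of wild-type library 1 (0.0812 and 0.162). The autophagy call was also lost with all pooled peaks (exact test, adjusted p = 0.123). With KQ, 3 basal genes (KRT6A, TP63 and MME) and 2 autophagy genes (GABARAP and SQSTM1) had a peak (exact test, adjusted p = 0.170 and 0.430). Basal epithelium was called with KQ over all pooled peaks (45.8% of genes, exact test, adjusted p = 0.00461), and autophagy with all peaks of KQ library 2 (23.1%, adjusted p = 0.0396).

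The other lists passed the threshold in neither group in the 50 kb window with reproducible peaks, but some did so under other settings. With wild type, luminal mammary epithelium had 14 of 23 genes with a peak (exact test, adjusted p = 0.0851), led by CDH1 and AGR2 (19.5). It was called in the 5 kb window (exact test, adjusted p = 0.0162) and with the nearest gene to each summit (0.00218). Angiogenesis and hypoxia had 14 of 22 (exact test, adjusted p = 0.0506), with FLT1 (17.3), ANGPT1 (16.1) and SEMA3C (13.2). It was called in the 5 kb window (exact test, adjusted p = 0.0333), with the nearest gene (2.81e-04) and with all peaks of wild-type library 1 (0.0117). ERBB and growth factor signalling had 17 of 30 (exact test, adjusted p = 0.0952), with AKT1 (24.4) and ERBB4 (15.6). It was called in the 5 kb window (exact test, adjusted p = 0.0423), with the nearest gene (4.60e-06), with all pooled peaks (0.00643) and with all peaks of wild-type library 2 (0.00380). Length matching was not run in these other wild-type settings. In the 50 kb window with reproducible peaks it gave an adjusted p of 0.138 for luminal epithelium, 0.173 for angiogenesis and 0.275 for ERBB (permutation test). Mesenchymal transition and matrix had 14 of 28, inflammatory mediators 13 of 26, Hippo and AP-1 11 of 20, cell cycle 11 of 25, apoptosis 11 of 24, stem cell with Wnt and Notch 11 of 26, cholesterol synthesis 10 of 24 and glycolysis 6 of 22. Of these, the matrix list was called with the nearest gene (exact test, adjusted p = 0.00665) and apoptosis with all pooled peaks (0.0275). Single genes of these lists with a strong wild-type peak within 50 kb were PLK1 (26.5), CDKN1C (20.9), MSMO1 (21.9), RELB (18.8) and CD44 (17.9). The CD44 peak lay inside the gene, and the others, like that of AKT1, lay outside the gene span. Among the comparison lists, ribosomal protein genes had 13 of 32, blood cell markers 10 of 26, hepatocyte markers 7 of 26 and neuron markers 6 of 24. In the 50 kb window with reproducible peaks, the adjusted p of the lists from mesenchymal transition onward lay between 0.364 and 1.000 (exact test).

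With KQ the remaining lists had between 0 and 2 genes with a reproducible peak. Cell cycle, glycolysis and inflammatory mediators had 0, although with all peaks of KQ library 2 the inflammatory list had 23.1% of its genes with a peak and was called (exact test, adjusted p = 0.0396). ZEB2 and COL4A1 of the matrix list, ANGPT1 and NDRG1 of the hypoxia list, and FOS and BATF of the AP-1 list had a peak. MED1, CD44, ELF5, BCL2L1, the hepatocyte marker ASGR1 and the neuron marker DLG4 were the single members of their lists with a KQ peak, and the blood cell marker CD14 had one. The MED1 peak is the CDK12 site, the ELF5 peak is the CAT site, and the ASGR1 and DLG4 peak is the ACADVL site.

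**Figure D3:**
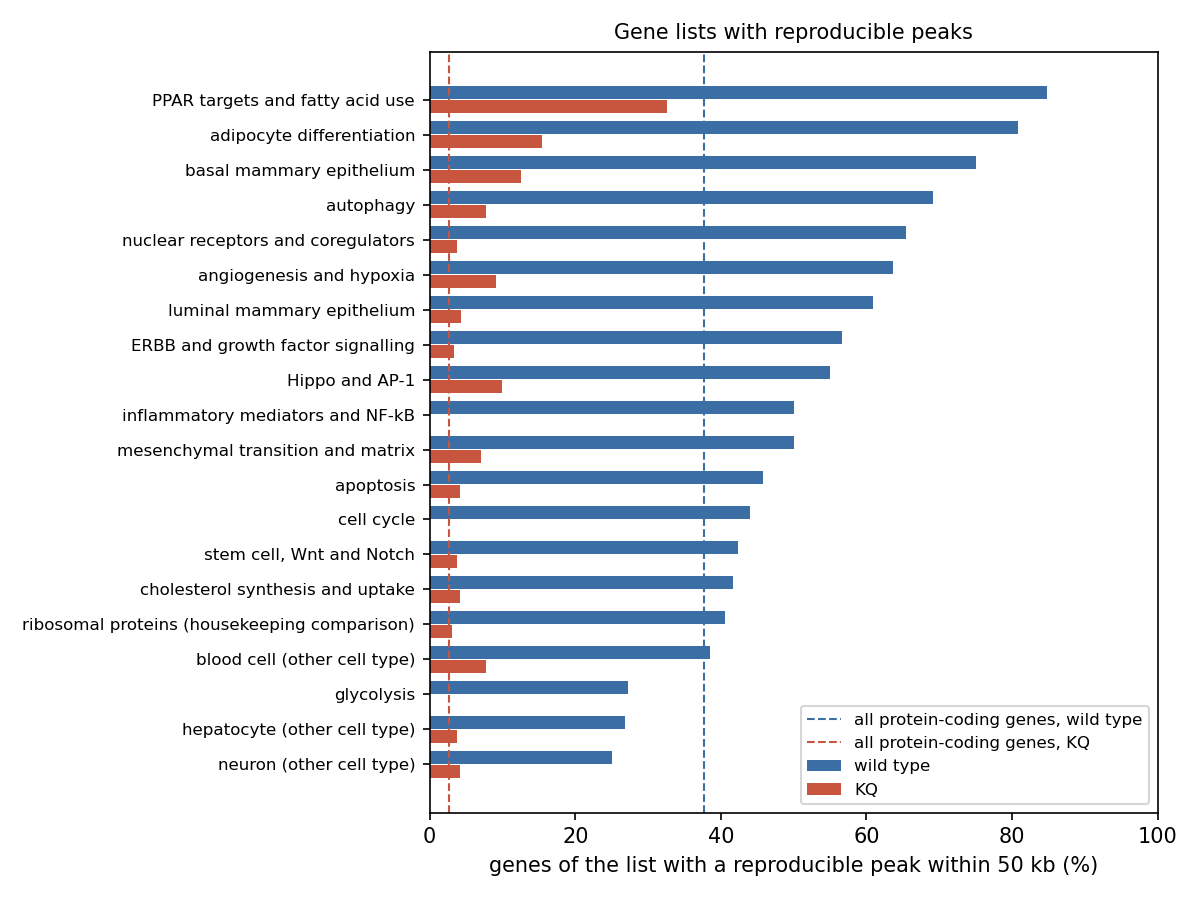
Share of the genes of each of the 20 lists, in percent, with a reproducible peak within 50 kb, for wild type (upper bar) and KQ (lower bar), with dashed lines at the share over all protein-coding genes. PPAR targets and fatty acid use reach 84.8% with wild type and 32.6% with KQ, against 37.7% and 2.68% of all genes.

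The location of the reproducible peaks relative to genes did not differ detectably between the groups. Summits at gene ends made up 5.54% of the reproducible wild-type peaks and 7.91% of the reproducible KQ peaks (Fisher's exact test, two-sided, p = 0.0758). Circular shifts gave 2.46% and 2.68%. Summits between genes made up 47.0% and 47.7% (exact p = 0.786), against 56.6% and 56.3% after shifts. Among all pooled peaks this share was 46.4% for wild type and 50.0% for KQ. It was 46.7% and 47.3% in the wild-type libraries and 50.6% and 48.7% in the KQ libraries. The reproducible wild-type list shortened to the KQ length had 41.0%. These further between-gene differences were not tested. In the single libraries the gene-end share was 6.18% and 6.96% for wild type and 6.41% and 5.31% for KQ. Over all pooled peaks the difference reversed, with 7.22% for wild type and 6.11% for KQ (exact p = 0.0283), and with all peaks of KQ library 2 against the reproducible wild-type peaks it was -0.23 points.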

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

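The tests of depth and of sites of the mutant's own were chosen only after their results were seen, and the test at matched list length was chosen after the peak counts were seen but before its own result.

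Peaks on the mitochondrial chromosome, which enters a comparison of the groups only where peaks on all sequences were counted, were found in all 4 ChIP libraries. There were 14 in wild-type library 1, 10 in wild-type library 2, 10 in KQ library 1 and 9 in KQ library 2, each above the limit of 3 that a count of 0 allows, which does not show binding. Their highest fold was between 1.39 and 3.89, below the median fold of 5.83 to 6.24 on the other chromosomes.

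The pattern weighed here is the low number of KQ peaks, with 15.7 times as many for wild type. Lower sequencing depth is argued against, because the lower KQ background rate, 3.56 tags per kb, lies above the higher wild-type rate of 2.69. This reading rests on a background on the scale of the ChIP tags. Whole pileups in 100% of peaks argue against ChIP tags scaled down to an input, but the use of an input is not given in the sources used here, and a background from an unscaled input would not measure ChIP depth. Loss of signal along a common ranking of sites stays open. With all 4 libraries shortened to 1035 peaks by q, the wild-type to KQ overlaps were 22.1% to 28.6%, all below the 31.3% of the KQ libraries with each other, but the highest did not lie below the interval of that value, which starts at 28.5%. The wild-type libraries shared 45.3% with each other at this length, above every wild-type to KQ value. Sites of the mutant's own cannot be told apart from weak peaks for the 508 KQ peaks in no wild-type list, of which 1.97% were in both KQ libraries against a range of 1.97% to 4.53% for KQ peaks of like q with wild-type overlap. The amount of mutant protein and the yield of the pull-down were not tested. The shortest peak, taken as the fragment length, was 142 and 128 bp with wild type and 170 and 165 bp with KQ. Fragment length thus differed with the group, and its part in the peak counts was not tested. The mutation itself remains an open explanation. Whether KQ peaks came from the cells' own receptor was not tested either, since the vector ChIP libraries were not analysed here.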

How the results depend on the processing

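The leave-out and block tests for covered length, the tests with single KQ libraries in the strength comparison, and those with length-matched and shortened gene lists were chosen after seeing the data. The ratio of peaks stayed between 14.3 and 23.5 under stricter q, all sequences and single libraries, and that of covered length between 12.2 and 15.9 with single libraries; the pooled lists, compared apart from these, gave 8.84 and 8.36. The replicate block cannot change a ratio of means taken on the log scale, so its 15.7 for peaks and 14.0 for covered length are no further check. Its exact sign-flip p of 0.5 is the smallest possible with 2 numbers. Between same-numbered libraries the ratio was 14.4 and 17.3 for peaks and 13.4 and 14.6 for covered length. The block gave 70.6% of KQ peaks in wild type and 4.53% of wild-type peaks in KQ. Nothing in the labels pairs the numbers, and deviations of same-numbered libraries had a correlation of -0.01 over 25721 regions. The KQ share in wild type was 72.1% to 88.4% under other overlap rules, q and reproducible peaks, 63% to 82.8% with single libraries, and 35.7% at matched length. The wild-type share in KQ was 3.91% for reproducible peaks, 35.6% at matched length and 3.31% to 11.2% with single libraries. Matching length by q keeps the strongest wild-type peaks, which overlap KQ most often; for the other values the cause was not tested. The strength difference was 1.39 on the log2 scale with −log10 q in place of fold and 0.48 to 0.70 with single libraries. The gene-end difference, KQ minus wild type, was 0.26 points within 5 kb and 0.85 at matched length. It was -1.11 for all pooled peaks and -0.23 to 1.73 with single libraries, lowest without KQ library 1; the cause was not tested. The wild-type lists called went from 5 to 2 at matched length, where fewer genes have a peak and the basal, autophagy and nuclear receptor calls ended. The autophagy odds ratio was not lower there, at 3.90 against 3.72. The wild-type lists called were 4 with length-matched lists, 6 in the 5 kb window, 7 with the nearest gene, 6 with all pooled peaks, 6 without wild-type library 1 and 4 without wild-type library 2. Calls were gained by the luminal, angiogenesis, ERBB, matrix and apoptosis lists under some of these settings. The KQ lists called went from 2 to 1 with the 5 kb window, with the nearest gene and with length-matched lists, where the adipocyte call ended. They were 3 with all pooled peaks, where basal epithelium was called, and between 2 and 4 with single libraries, highest without KQ library 1, where all peaks of KQ library 2 replace the reproducible ones and autophagy and inflammatory mediators were called; the cause was not tested. The PPAR list passed in every setting run, with a wild-type odds ratio of 9.24 that was 19.7 at matched length and 5.73 to 9.30 with single libraries, lowest without wild-type library 2; the cause was not tested. Of 74 alternatives of results that answer a comparison, 54 stayed the same, 18 moved and 2 reversed. Among the called lists, only the PPAR list had its odds ratios in this count. The lost calls of the other lists enter it only through the number of lists called. Of 79 named genes with a wild-type peak, 34 had none in the 5 kb window, and of 33 with a KQ peak, 13 had none. Leaving out a library has no counterpart for the overlap between replicates. The motif alternatives were not run. The vector and input libraries were not analysed here, and 2 libraries per group allow no exact p below 0.33.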

Other observations

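The finer strength matching and the comparison of all 20 lists in this part were chosen only after the results were seen, and the first test of the PPAR list was set before its result was seen.

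The 100 reproducible wild-type peaks with the highest −log10 q mark where KQ overlap was most common and where it failed. Of these, 90 overlapped a pooled KQ peak and 10 overlapped no KQ list. The 10 lay nearest to CDK11A, ARHGEF7, RBBP5, PROX1, ZNF496, PTPRG, STK10, TP53I13, VPS13D and KALRN, with folds from 13.8 to 35.2. PRKCH, a protein kinase C, had 11 reproducible wild-type peaks in its window and 1 reproducible KQ peak, which overlapped no wild-type list. DLGAP1 had 10 with wild type and 0 with KQ, and DUSP1, a MAP kinase phosphatase, had 9 and 0. ZEB2 had 9 and 2. LAMA4, a laminin chain, had the most reproducible KQ peaks, 3, beside 7 with wild type, and DECR1, an enzyme of unsaturated fatty acid oxidation, had 2 with each. These genes were chosen after their values were seen.

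The 10 reproducible KQ peaks in no wild-type list lay nearest to LOC124902536, SLC35C1, PRKCH, SPRED1, TUBD1, PPP1R21, BCAS1, PAXBP1, SOX2 and EEPD1. Their folds were 4.69 to 8.50. The assignments to SOX2, LOC124902536 and EEPD1 span 498.2, 173.2 and 104.9 kb, and the others at most 36.3 kb. The share of reproducible peaks per chromosome differed between the groups on 0 of 23 chromosomes (Fisher's exact test, lowest adjusted p = 0.689, and 0 with an unadjusted p under 0.05). The shortest peak, a measure of the fragment length, was 142 and 128 bp in the wild-type libraries and 170 and 165 bp in the KQ libraries.

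Reproducible wild-type peaks near PPAR targets and fatty acid genes were found again with KQ more often than others. Of 86 such peaks, 37 (43.0%) overlapped a pooled KQ peak, against 19.9% of the other reproducible wild-type peaks. Peak strength alone would give 20.9% to 37.2% in 10000 draws of other peaks matched on 10 bins of q, so for this list taken alone it is argued against as the whole account; matching in 80 bins narrowed the margin, with 25.6% to 41.9% for q (permutation p = 0.0278) and 18.6% to 36.0% for fold. Over all 20 lists the adjusted p of the PPAR list was 0.0600, and 0 lists passed, with 2 lists under 0.05 unadjusted (permutation test). The other of these was cell cycle, with 0 of 15 peaks found again (permutation test, adjusted p = 0.0740).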
